A study of Mus musculus with 2 samples.

How the data were processed

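The series holds total RNA-seq of hippocampal tissue from male B6CASTF1/J mice aged 18 to 20 months, 2 libraries in 1 group, each made from 300 ng of RNA, per the labels. Samples were grouped by the strain, sex, age and tissue in the labels, and the replicate numbers were taken from there. Per the labels, RNA was extracted with a kit for animal tissue, and the ERCC spike-in profile is one for stranded libraries with ribosomal RNA reduced.

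For each library the authors deposited a table per gene and 2 tables per transcript. Per the deposited notes that come with them, the reads were compared with the mouse assembly mm10 and GENCODE M21; the tool names and versions are not given in the sources used here. Per the file headers, the gene table and the first transcript table, which were derived from an alignment to the transcriptome, have the column layout of RSEM and give an expected count and TPM; the second transcript table was derived from the reads directly, has the layout of kallisto and gives an estimated count and TPM. The percent of a gene's expression held by each transcript and a score for the spread of each expected count, its posterior SD, were also deposited by the authors. Whether counting used strand is not stated there for each table, so genes that overlap on opposite strands are uncertain. Near-identical genes share reads, and the deposited expected count splits them by a model, so such genes are named as uncertain. The assembly represents C57BL/6J, so reads of the CAST/EiJ allele can align less well; alleles were not analysed here.

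The gene table holds 55536 gene rows, all matched to the annotation, 96 ERCC rows, 1 phiX row and 26248 rows named by a number only, laid out like transfer RNA entries. Non-gene rows stayed out of library sizes and shares. The ERCC rows took 0.418% of all counts in replicate 1 and 0.479% in replicate 2. Expected counts over genes came to 34563482 and 32370292, and those of the second table summed per gene to 34854528 and 32438168. Symbols with several gene rows, 115 in all, were represented in the gene lists by the row with the highest mean TPM; Dlx6os1 was the only list member concerned. Intervals of ratios are 95% Clopper-Pearson intervals of the share of counts, and floors rest on 3 counts; both cover counting error only, since reads without molecular identifiers are not independent molecules.

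Levels are the deposited TPM. Detection meant a TPM of at least 1 in both libraries. Before the data were examined, 48 gene lists, the rule for genes named and the alternatives were fixed; X inactivation, with only Xist and Tsix, had too few members for a median, for which 3 were needed. Each list's median of mean TPM was placed among 10000 random lists of the same size drawn from genes with a mean TPM of at least 0.1. The genes named are the 15 protein-coding and 5 other nuclear genes with the highest mean TPM, the up to 4 highest members and the lowest member of each list, members of receptor families, the 10 genes with the largest ratio in each direction and 20 genes for transcripts; not every gene that the rule names is reported here.

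To compare the libraries, expected counts were rounded to whole numbers and normalized by TMM in edgeR 4.0.16 (R 4.3.3); the common dispersion was estimated with an intercept only over genes with a mean CPM of at least 1. Log2 ratios used a prior count of 0.5. Genes differing at least 2-fold were counted at a mean CPM of at least 5. For each list with at least 3 members at a mean CPM of at least 1, the median log2 ratio was placed among 10000 random lists matched on expression in 20 bins, and lists outside the central 95% were said to stand apart; this describes the 2 libraries only. The leading transcript of a gene was compared between the tables for genes with a TPM of at least 1 and several transcripts. Protein lengths are those of the annotated coding sequence. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and sequence copies were searched with blastn 2.17.0.

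The steps were tested on simulated data with the real genes, means and library sizes of this replicate comparison, 55536 genes, a biological coefficient of variation of 0.05 and 200 changed genes. Of the genes that passed the minimum, 66 of 66 changed 4-fold, 66 of 67 changed 2.5-fold and 0 of 67 changed 1.5-fold were counted at 2-fold or more, as were 0 of 11213 unchanged genes. The coefficient recovered with no changed gene was 0.0499, and with the changed genes 0.0990. Of 45 lists, the shifted one alone stood apart. Its simulated shift was 1.5-fold, a log2 ratio of 0.585, and genes were drawn independently of each other. Apart from the choroid plexus list, the lists that stood apart in the real data had smaller medians, so the simulation does not test calls of their size.

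Alternatives were DESeq2 1.42.0 size factors, spike-in scaling, other minimum levels, unmatched random lists, list means, counts without length correction, TPM rescaled over protein-coding nuclear genes, the second transcript table summed per gene, and leaving out each replicate.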

Results

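Total RNA was measured in hippocampal tissue of male B6CASTF1/J mice, hybrid offspring of the C57BL/6J and CAST/EiJ strains, at 18 to 20 months of age. The labels give 1 group with 2 biological replicates, replicate 1 and replicate 2. These are separate tissue samples under a shared donor record, and the labels do not say whether they came from separate animals. Expected counts over annotated genes came to 34563482 in replicate 1 and 32370292 in replicate 2. A count of 0 therefore allowed a level of up to 0.0868 CPM (counts scaled to library size) in replicate 1 and 0.0927 CPM in replicate 2. Levels below are in TPM (transcript abundance corrected for length), as the mean ± SD over the 2 replicates (n = 2). With 1 group there was no comparison between conditions; the comparisons are between genes and gene lists within the tissue, and between the 2 libraries. The smallest two-sided p that an exact sign-flip test of 2 values can give is 0.5, so no p-values are reported, and each difference is set beside the SD. The replicates were not copies of a single library: the chi-square statistic of their counts was 8.46 per degree of freedom over 17948 genes. Over the ERCC RNA spike-ins, synthetic RNAs added to the samples, it was 1.26.

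Of 55536 annotated genes, 14287 had a TPM of at least 1 in both replicates, and 12673 of these were protein-coding. Small structural RNAs took a large share of the TPM and a far smaller one of the counts. Rn7s1 and Rn7s2, near-identical genes of the 7SL RNA of the signal recognition particle on chromosome 12, each stood at 148652 ± 1148 TPM, with reads that the quantification could not tell apart. Together they held 29.8% of the gene TPM in replicate 1 and 30.2% in replicate 2, but 4.32% and 4.28% of the expected counts. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, stood at 55222 ± 389 TPM. A second quantification, by transcript, gave Rn7s1 0 and 0.426 TPM and Rn7sk 1.36 and 0 TPM, so their levels rest on the quantification. Gm26917, annotated as a long noncoding RNA gene on chromosome 17, stood at 12171 ± 591 TPM. Which RNA its reads come from was not tested, so this level is uncertain too. Gm28661, a pseudogene on chromosome 1 that shares sequence with the mitochondrial gene mt-Co2, stood at 7245 ± 199.6 TPM. The level of Gm28661 is uncertain because it rests on how the quantification divided the reads. Mitochondrial genes took 9.81% ± 1.23 of the expected counts, 10.7% in replicate 1 and 8.94% in replicate 2. The ribosomal RNAs mt-Rnr2, at 51539.6 ± 6415 TPM, and mt-Rnr1, at 39710.2 ± 7019 TPM, made up most of this share. Mitochondrial messenger RNAs took 1.87% in replicate 1 and 1.86% in replicate 2, so the replicates differed in the mitochondrial ribosomal RNAs, at 8.81% and 7.09%. Gm28661 was counted as nuclear and held 103766 counts in replicate 1 and 99159 in replicate 2, against 3578 and 1979 for mt-Co2. If its reads came from mt-Co2, the share of mitochondrial messenger RNAs is too low in both.

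Among nuclear protein-coding genes the highest level was that of Fth1, the heavy chain of the iron store ferritin, at 1504 ± 39.5 TPM. Camk2a followed at 1416 ± 17.4 TPM. It codes for the alpha subunit of the synaptic calcium/calmodulin-dependent kinase and lies on chromosome 18 from 60925618 to 60988152 (mm10). Camk2a-207, a 530-base transcript with an incomplete coding sequence, held 27.3% of the Camk2a TPM, and 22.2% in the second quantification. The rank of Camk2a is therefore not one of complete coding transcripts. Hpca, the neuronal calcium sensor hippocalcin, stood at 1098 ± 44.7 TPM, and Snap25, a SNARE protein of synaptic vesicle fusion, at 947 ± 70.8 TPM. Calm2, which codes for calmodulin, reached 938 ± 43.3 TPM, and Cpe, a carboxypeptidase of neuropeptide processing, 1106 ± 68.6 TPM. The glial and secreted products Apoe, a lipid carrier, and Cst3, a protease inhibitor, stood at 1077 ± 22.7 and 1057 ± 30.6 TPM. Other genes among the top 15 were Eef1a1 (1290.4 ± 36.1 TPM), Actb (1284 ± 23.2 TPM), Aldoa (1141 ± 69.5 TPM), Gapdh (1091 ± 93.8 TPM), Snurf (985 ± 48.1 TPM) and Hspa8 (983 ± 47.7 TPM), genes of translation, cytoskeleton, glycolysis, the imprinted Snrpn locus and protein folding.

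Markers of excitatory neurons stood well above those of inhibitory neurons. The 6 excitatory genes had a median of 326 ± 20.4 TPM, led by Camk2a, Nrgn (628 ± 15.03 TPM), a calmodulin-binding postsynaptic protein, and Slc17a7 (579 ± 36.5 TPM), the vesicular glutamate transporter VGLUT1. The 7 inhibitory genes had a median of 29.1 ± 1.52 TPM, led by Gad1 (151 ± 1.78 TPM), which codes for a GABA-synthesising enzyme. The log2 ratio of the list medians was 3.48 ± 0.02 (SD, n = 2), an 11.2-fold difference far beyond the SD between the libraries. That SD does not cover the choice of genes. The lists hold different genes, so the ratio does not compare numbers of cells. The size of the log2 ratio also rests on the measure. With counts not corrected for length it was 2.71 and with the mean of log2(TPM + 1) 2.56. For single genes, Slc17a7 was 3.84 ± 0.197 times Gad1, and Gad1 was 4.26 ± 0.238 times Gad2. Among 11 markers of interneuron subclasses (median 25.9 ± 2.42 TPM), the peptides Cck (271 ± 18.4 TPM) and Sst (179 ± 16.6 TPM) led, followed by the cannabinoid receptor gene Cnr1 (74.1 ± 5.11 TPM) and Npy (52.3 ± 8.02 TPM). Vip had the lowest level, 6.21 ± 0.955 TPM, and Sst was 29.0 ± 1.78 times as high. The 10 pan-neuronal genes, among them Syt1 (424 ± 23.1 TPM), Eno2 (420 ± 2.86 TPM) and Map2 (415 ± 15.2 TPM), had a median of 184 ± 12.7 TPM. Against the pooled astrocyte, oligodendrocyte and microglia genes their log2 ratio was 2.15 in replicate 1 and 2.25 in replicate 2, a 4.60-fold difference on average. It moved with the measure too, to 2.81 with counts not corrected for length and 2.38 with the mean of log2(TPM + 1). These lists hold different genes as well.

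The principal fields of the hippocampus were represented unequally in the marker lists. The CA1 pyramidal list had a median of 50.3 ± 0.544 TPM, with Mpped1 (74.2 ± 0.134 TPM), Wfs1 (67.7 ± 5.75 TPM) and Fibcd1 (50.3 ± 0.544 TPM) at the top. The dentate granule list had a median of 29.4 ± 1.51 TPM, led by Stxbp6 (35.5 ± 3.44 TPM) and Dock10 (33.8 ± 3.01 TPM), with the granule cell transcription factor Prox1 at 29.4 ± 1.51 TPM. The CA3 list stood at 22.1 ± 2.98 TPM, where Cpne4 reached 54.3 ± 3.29 TPM and Bok 25.6 ± 3.30 TPM. The CA2 list stood at 5.12 ± 0.0919 TPM, although Pcp4, a calmodulin regulator, reached 92.4 ± 4.91 TPM and Rgs14 44.5 ± 0.368 TPM. The mossy cell list stood at 2.92 ± 0.297 TPM. Over members with a TPM of at least 1 only, the CA2 and mossy cell medians were 9.315 and 8.675 TPM. Lists of neighbouring regions had medians of 12.02 ± 0.170 TPM (neocortex, led by Fezf2 at 19.7 ± 1.34 TPM), 4.995 ± 0.672 TPM (thalamus, led by Prkcd at 14.1 ± 1.252 TPM) and 2.69 ± 0.216 TPM (striatum, led by Ppp1r1b at 25.6 ± 2.83 TPM; 4.185 TPM over members with a TPM of at least 1). Slc17a6, the vesicular glutamate transporter VGLUT2 of thalamic neurons, differed between the libraries at 4.38 ± 1.53 TPM. These lists hold different genes, so their medians do not rank the number of cells.

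Astrocyte and oligodendrocyte genes were the most abundant glial groups. The 11 astrocyte genes had a median of 63.3 ± 1.93 TPM, led by the glutamate transporter Slc1a2 (701 ± 8.95 TPM), the aldolase Aldoc (343 ± 7.58 TPM) and the intermediate filament gene Gfap (173 ± 1.26 TPM). The 10 oligodendrocyte genes had a median of 56.6 ± 1.08 TPM, among them the myelin genes Mbp (684 ± 27.5 TPM) and Mobp (171 ± 2.75 TPM). The 11 microglia genes stood at 16.5 ± 0.509 TPM, with the receptor gene Csf1r at 31.1 ± 1.20 TPM. Oligodendrocyte precursor genes had a median of 6.21 ± 0.467 TPM, with Pdgfra at 12.7 ± 0.219 TPM. Endothelial genes stood at 5.81 ± 0.247 TPM, with Ly6c1 at 25.2 ± 2.36 TPM, and mural cell genes at 3.50 TPM in replicate 1 and 1.71 TPM in replicate 2, with Vtn at 19.3 ± 2.11 TPM. Genes of red blood cells stood at 91.5 ± 13.8 TPM, with the globin gene Hba-a1 at 122 ± 5.20 TPM; the globin genes share reads with near-identical copies. Meningeal fibroblast genes, led by the growth factor gene Igf2, had a median of 2.43 ± 0.255 TPM, ependymal genes 1.69 ± 0.308 TPM and perivascular macrophage genes 0.595 ± 0.0495 TPM. Lymphocyte genes had a median of 0.0100 ± 0.0141 TPM, and none of the 8 reached a TPM of 1 in both libraries. Choroid plexus genes differed between the libraries, with a median of 0.705 TPM in replicate 1 and 4.42 TPM in replicate 2. Of the 47 gene lists with a median, 17 stood above the range that holds the central 95% of 10000 random lists of the same size, and 3 (lymphocyte, adult neurogenesis and senescence) stood below it. Random lists were drawn only from genes with a mean TPM of at least 0.1, while list members were not filtered this way. The lymphocyte median, 0.0100 TPM, therefore had to fall below, and the senescence median, 0.115 TPM, nearly had to. No conclusion is drawn from the 3 low placings. The medians themselves rest on the scale: with TPM rescaled over protein-coding nuclear genes all 47 were higher, 2.40 times at the median, and in the second quantification 37 moved by over 1.5 times. The pan-neuronal median was then 443 and 276 TPM, and the excitatory one 782 and 505 TPM.

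**Figure D1:**
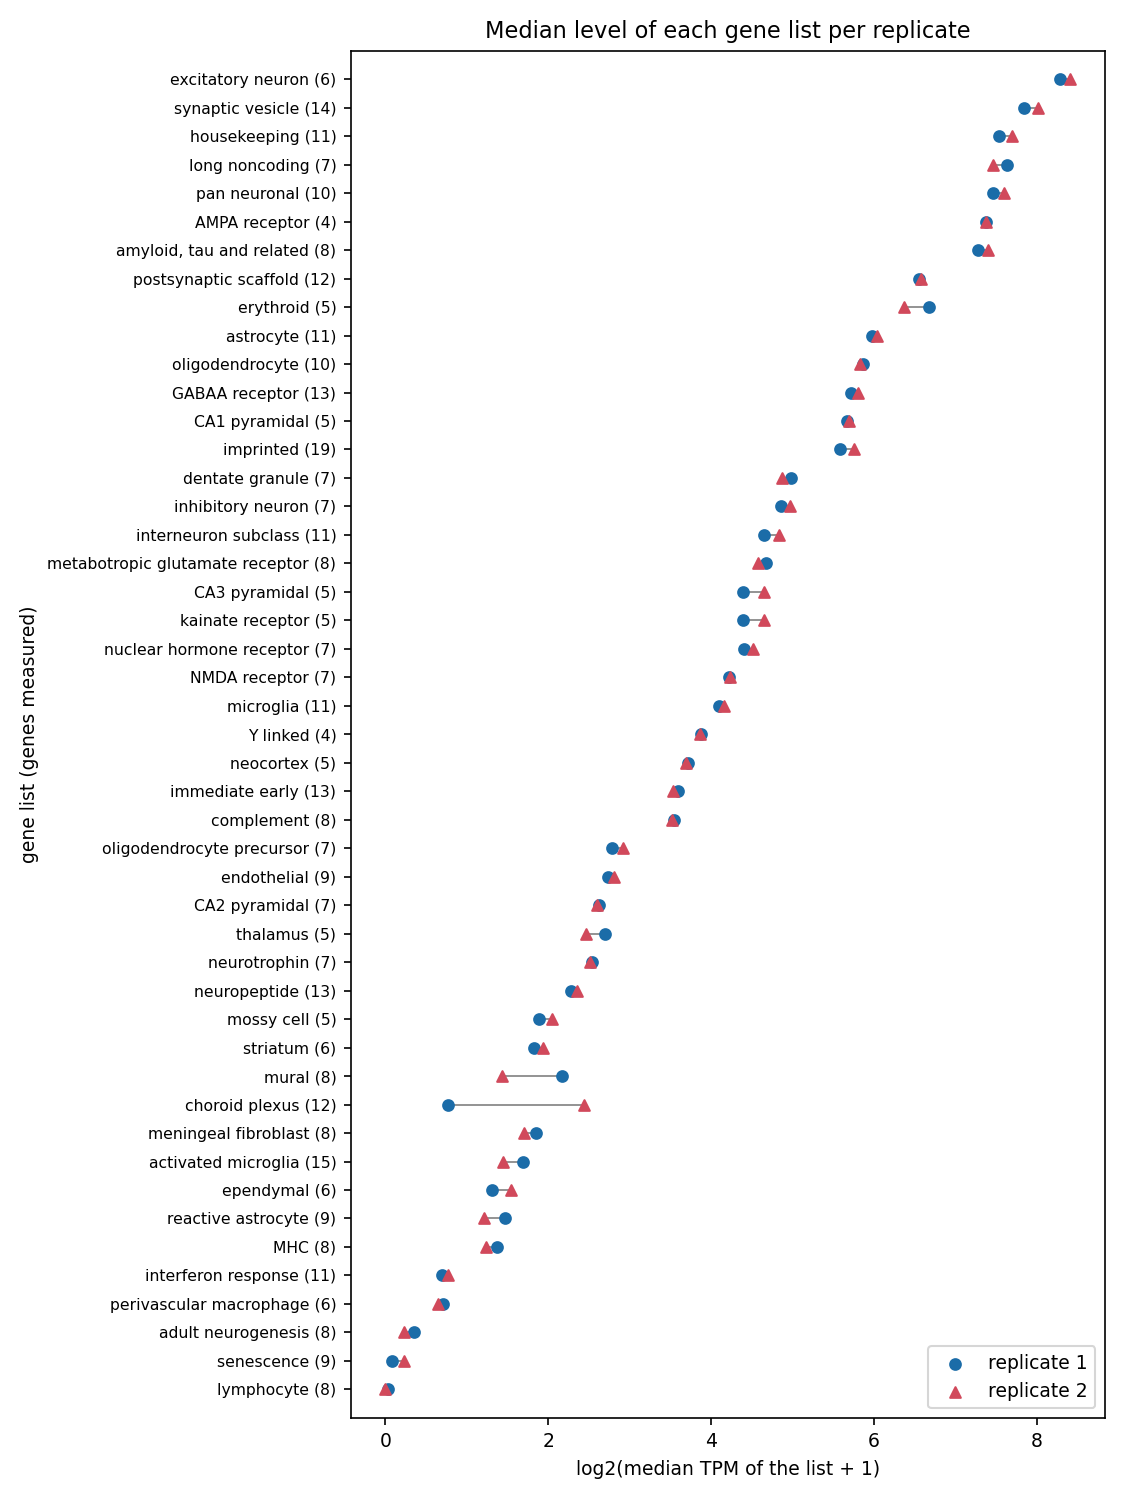
Median level of each of 47 gene lists in replicate 1 (circles) and replicate 2 (triangles), on the scale log2(median TPM + 1), with the number of genes measured in brackets. The excitatory neuron list has the highest median, 326 TPM on average, and the choroid plexus list shows the widest gap between the replicates, 0.705 against 4.42 TPM.

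Glutamate and GABA receptor families were each dominated by a few subunit genes. The median levels of the 5 families were 164.6 ± 0.00354 TPM (AMPA), 17.7 ± 0.0778 TPM (NMDA), 22.1 ± 2.98 TPM (kainate), 23.7 ± 1.09 TPM (metabotropic glutamate) and 53.3 ± 2.00 TPM (GABA-A). The AMPA median lies midway between Gria2 and Gria3, which moved in opposite directions between the libraries. Each of these genes had an SD of 2.09 TPM, so the SD of the AMPA median understates the spread. Over members with a TPM of at least 1 the NMDA median was 70.4 TPM, the second highest, so it does not rank the families. Of the AMPA receptor genes, Gria1 (292 ± 4.72 TPM) and Gria2 (266 ± 2.09 TPM) held 45.4% ± 0.286 and 41.3% ± 0.733 of the family's TPM. Gria2 stood at 0.910 ± 0.0219 of Gria1. Transcripts coding for 907 amino acids held 97.9% ± 1.02 of the Gria1 TPM, but those coding for 883 amino acids only 70.6% ± 1.20 of the Gria2 TPM. Retained-intron transcripts, led by Gria2-208 at 11.2%, count toward the Gria2 level, so the near-equal gene levels are not levels of coding transcripts. Gria3 (63.3 ± 2.09 TPM) and Gria4 (21.7 ± 1.63 TPM) followed. Of the NMDA receptor genes, the obligate subunit Grin1 stood at 168 ± 1.44 TPM, Grin2a at 137 ± 3.46 TPM and Grin2b at 123 ± 7.41 TPM. Grin2a was 1.12 ± 0.0390 times Grin2b. Grin2c (17.7 ± 0.0778 TPM), Grin3a (12.7 ± 0.587 TPM) and Grin2d (4.29 ± 0.0849 TPM) were far lower, and Grin3b had 5 counts in replicate 1 and 0 in replicate 2. Of the kainate receptor genes, Grik5 led at 89.0 ± 0.269 TPM, 2.52 ± 0.0561 times Grik2 and 4.06 ± 0.534 times Grik4. Grik1 was the lowest, at 4.75 ± 0.488 TPM. Of the metabotropic receptor genes, Grm5 held 48.1% ± 0.458 of the family's TPM at 100.1 ± 2.27 TPM, and Grm3 (26.5 ± 1.55 TPM), Grm7 (24.2 ± 0.976 TPM) and Grm2 (23.5 ± 3.63 TPM) stood well below it. Grm6, the receptor of retinal bipolar cells, had 0 counts in both libraries. Of the GABA-A receptor genes, Gabra5, a subunit of extrasynaptic receptors in the hippocampus, stood at 73.2 ± 1.99 TPM. Gabrd, another subunit of extrasynaptic receptors, stood at 10.3 ± 0.354 TPM. Gabra6, a subunit of cerebellar granule cells, had 6 counts in replicate 1 and 4 in replicate 2.

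**Figure D2:**
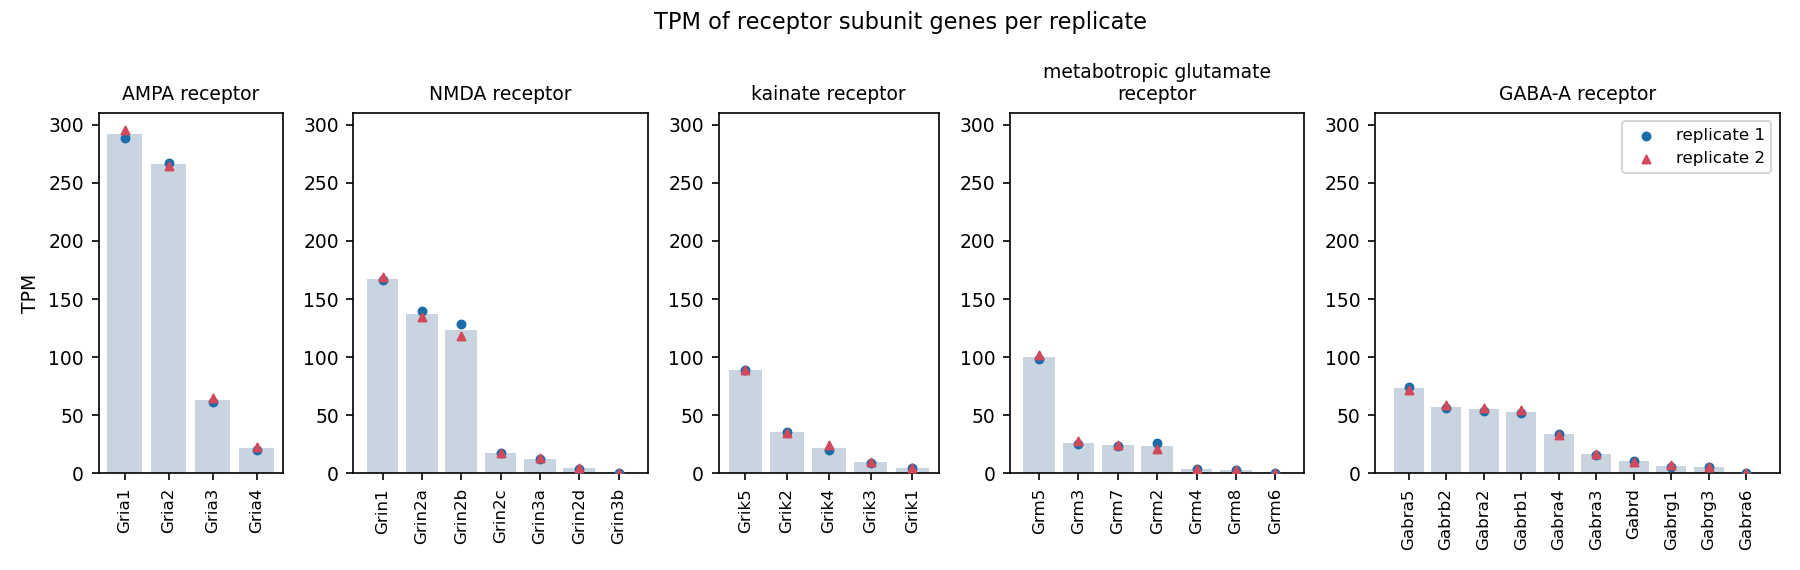
TPM of subunit genes of the glutamate and GABA-A receptor families; bars show the mean of the 2 libraries, circles replicate 1 and triangles replicate 2. Gria1 and Gria2 reach the highest levels, 292 and 266 TPM, above Grin1 at 168 TPM.

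Genes of the presynaptic and postsynaptic apparatus were abundant. The 14 synaptic vesicle genes had a median of 243 ± 21.6 TPM, led by Snap25, the vesicle protein gene Syp (751 ± 67.8 TPM), Syt1 and Vamp2 (407 ± 21.1 TPM). The 12 postsynaptic scaffold genes had a median of 94.0 ± 1.03 TPM, led by Dlg4, which codes for PSD-95 (340 ± 8.48 TPM), Shank1 (261 ± 4.41 TPM) and Dlgap1 (211 ± 3.93 TPM). Dlg4 was 3.66 ± 0.0269 times Dlg2, a scaffold gene of the same family. Among 13 neuropeptide genes (median 3.995 ± 0.191 TPM), Cck, Sst, Npy and the enkephalin precursor gene Penk (22.0 ± 0.382 TPM) led and Crh was the lowest at 1.03 ± 0.255 TPM. The list of neurotrophins and their receptors had a median of 4.77 ± 0.0707 TPM, or 13.1 TPM over members with a TPM of at least 1. Its receptors Ntrk2 (137 ± 8.17 TPM) and Ntrk3 (74.5 ± 3.29 TPM) stood far above the ligand genes Bdnf (13.1 ± 0.0849 TPM) and Ntf3 (4.61 ± 0.290 TPM). The list of nuclear hormone receptors had a median of 21.1 ± 1.19 TPM. The thyroid hormone receptor gene Thra stood at 454 ± 22.4 TPM, 21.6 ± 0.154 times Thrb. The mineralocorticoid receptor gene Nr3c2 (61.9 ± 2.89 TPM) was 1.88 ± 0.0962 times the glucocorticoid receptor gene Nr3c1 (32.97 ± 0.148 TPM), and the oestrogen receptor gene Esr2 had the lowest level, 0.105 ± 0.0495 TPM.

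Groups named in studies of ageing brain were measured without a younger group beside them, so only levels are given. The 15 genes of activated microglia had a median of 1.97 ± 0.354 TPM; Apoe, Ctsb (171 ± 13.7 TPM), Ctsd (128 ± 11.7 TPM) and Cd9 (22.0 ± 2.09 TPM), which other cells also express, were the highest, and Ccl4 had 0 counts in both libraries. Complement genes had a median of 10.6 ± 0.0919 TPM, with C4b at 29.0 ± 0.346 TPM and C1qb at 23.0 ± 1.02 TPM. Interferon response genes stood at 0.665 ± 0.0636 TPM, where Ifi27 reached 49.5 ± 3.78 TPM. Antigen presentation (MHC) genes stood at 1.47 ± 0.159 TPM, with B2m at 47.7 ± 3.58 TPM and H2-K1 at 10.6 ± 0.707 TPM. Reactive astrocyte genes stood at 1.55 ± 0.325 TPM, with Serpina3n at 33.05 ± 0.813 TPM and Vim at 23.0 ± 0.240 TPM. Senescence genes had a median of 0.115 ± 0.0778 TPM, 0.06 in replicate 1 and 0.17 in replicate 2; the cell cycle inhibitor gene Cdkn1a stood at 10.3 ± 0.827 TPM, and Cdkn2a had 3 counts in replicate 1 and 4 in replicate 2. The 8 genes of amyloid, tau and related proteins had a median of 161 ± 9.61 TPM, led by Aplp1 (577 ± 21.8 TPM), App (550 ± 31.7 TPM) and Aplp2 (185.9 ± 6.44 TPM). Genes of adult neurogenesis had a median of 0.225 ± 0.0707 TPM. Among them Neurod1 stood at 12.1 ± 0.0778 TPM, Sox11 at 5.40 ± 0.629 TPM and Dcx, a microtubule protein of immature neurons, at 2.40 ± 0.255 TPM. Eomes, of intermediate progenitors, had 5 counts in replicate 1 and 0 in replicate 2. Members near 0 lower several of these medians: over members with a TPM of at least 1 they were 16.6 TPM for activated microglia, 19.4 for complement, 5.955 for interferon response, 9.34 for antigen presentation and 5.395 for adult neurogenesis.

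Activity-dependent, imprinted, noncoding and sex-linked genes were measured in the same way. The 13 immediate early genes had a median of 10.9 ± 0.368 TPM, led by Arc (86.8 ± 8.10 TPM), Egr1 (46.0 ± 6.49 TPM), Egr3 (42.7 ± 1.39 TPM) and Nr4a1 (38.3 ± 4.24 TPM). The 19 imprinted genes had a median of 50.01 ± 4.30 TPM. Of these, the maternally expressed noncoding RNAs Meg3 and Rian stood at 802 ± 31.4 and 365 ± 5.90 TPM, the G protein subunit gene Gnas at 797 ± 59.5 TPM and Snrpn at 345 ± 20.5 TPM. The 7 long noncoding RNA genes had a median of 186.5 ± 14.8 TPM, with the nuclear RNA Malat1 at 3810.0 ± 411 TPM. The 4 Y-linked genes had a median of 13.7 ± 0.0919 TPM, with Eif2s3y at 24.8 ± 0.0354 TPM and Ddx3y at 18.2 ± 0.276 TPM. Xist, the RNA of X inactivation in females, had 7 counts in replicate 1 and 8 in replicate 2, and its antisense partner Tsix stood at 0.130 ± 0.0141 TPM. Housekeeping genes had a median of 195 ± 14.96 TPM.

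Choroid plexus genes set the 2 libraries apart more than any other list. All 11 members with a mean CPM of at least 1 were higher in replicate 2, and the list's median log2 ratio of replicate 1 over replicate 2 was -2.74, a 6.67-fold difference, below each of 10000 random lists matched on expression. Over the 5 members with a mean CPM of at least 5 it was -1.92, a 3.79-fold difference. Ttr, the thyroid hormone carrier secreted by choroid plexus epithelium (chromosome 18, 20665280 to 20674321, mm10), stood at 29.9 TPM in replicate 1 and 672 TPM in replicate 2. Its log2 ratio was -4.44 (95% Clopper-Pearson interval -4.55 to -4.34, counting error only). Enpp2, the enzyme autotaxin, differed by a log2 ratio of -1.39 (-1.44 to -1.33), the prolactin receptor gene Prlr by -1.92 (-2.21 to -1.65), and the chloride channel gene Clic6 by -2.57 (-3.00 to -2.19). These comparisons, and those that follow, compare libraries, not conditions.

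Over all genes, the libraries lay close together. The edgeR common biological coefficient of variation was 4.98% over 14887 genes with a mean CPM of at least 1, and 1.79% over the ERCC spike-ins. Without the genes of the choroid plexus lists, an alternative chosen after seeing the data, it was 3.87%. Across those 14887 genes, which are not independent replicates, Pearson's r and Spearman's rho between the libraries were both 0.994. Of 11418 genes with a mean CPM of at least 5, 95% differed by less than 1.18-fold and 16 differed at least 2-fold, 13 higher in replicate 2 and 3 higher in replicate 1. With spike-in scaling, the split was 10 and 6. The 3 higher in replicate 1 were the processed pseudogenes Gm13370, Gm10240 and Gm13394, with 496, 496 and 594 counts against 0, whose counts have a large deposited posterior SD and are uncertain, as are those of Gm14760, Gm12070, Pagr1a and Fam220a. Besides Ttr, Enpp2, Prlr and Clic6, those higher in replicate 2 were F5, the coagulation factor V gene (log2 ratio -2.97), Ace, the angiotensin-converting enzyme gene (-1.47), Pagr1a (-1.29), the pseudogenes Gm12070 (-1.22) and Gm14760 (348 counts against 0) and 1 of the overlapping Fam220a entries (-1.72). The rest were Col9a3, Vat1l and Gm10163, named after their values were seen. Under the 2-fold mark, Xlr3b (0.92), Ptgds, a prostaglandin D synthase (0.89), and mt-Co2, a subunit of cytochrome c oxidase (0.78), had higher counts in replicate 1. Leaving out pseudogenes and genes with an uncertain count, an alternative chosen after seeing the data, left 8 genes, all higher in replicate 2. With the minimum at a mean CPM of 1 the count was 77.

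Of 45 lists tested, 15 stood apart between the libraries, where 2.25 would be the number for lists of unrelated genes. Genes of a list can move together and some lists share members, so 2.25 is not the number to expect for these lists. Higher in replicate 1 were meningeal fibroblast genes (median log2 ratio 0.31), mural cell genes (0.30), red blood cell genes (0.24), immediate early genes (0.24), thalamus genes (0.21), long noncoding RNAs (0.21), dentate granule genes (0.17) and oligodendrocyte genes (0.07). The 8 mural, 5 red blood cell and 7 dentate granule genes were all higher in replicate 1, as were 11 of 13 immediate early genes, among them Egr1 (0.34) and Arc (0.24). Malat1 had a log2 ratio of 0.31 and the thalamus marker Prkcd of 0.21. Transcripts annotated as intronic (median 0.24 over 43 genes) or unconfirmed (0.26 over 495) moved the same way, and antisense ones (0.06 over 167) and all long intergenic RNAs (0.05 over 251) less so, as did transcripts with a retained intron against the coding transcripts of the same gene, 0.18 over 4775 genes. Higher in replicate 2, besides the choroid plexus genes, were ependymal genes (-0.39), neuropeptide genes (-0.14), interneuron subclass genes (-0.10), kainate receptor genes (-0.10), synaptic vesicle genes (-0.09) and pan-neuronal genes (-0.09). Scaling by the spike-ins moved the ratios of all genes by 0.18 toward replicate 1; the medians of the last 5 of these lists then lay between 0.04 and 0.09, above 0, while still below the central 95% of matched lists. Of the 14 synaptic vesicle genes, 13 were higher in replicate 2 before that scaling, Snap25 at -0.11 and Syp at -0.10. Of the 15 lists, 8 stood apart in every setting tried. Without members shared between lists, chosen after seeing the data, the pan-neuronal, interneuron subclass, kainate receptor and neuropeptide lists no longer did, which left 3 higher in replicate 2. The kainate receptor and neuropeptide calls also ended with list means, and the kainate receptor call with unmatched random lists. The ependymal call ended with list means, and with spike-in scaling where 1 of its 5 members fell below the minimum; with all 5 kept, chosen after seeing the data, it held at -0.21. The mural cell call ended in the second transcript table (0.16) and with members at a mean CPM of at least 5 (0.12), and the oligodendrocyte call with unmatched random lists.

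**Figure D3:**
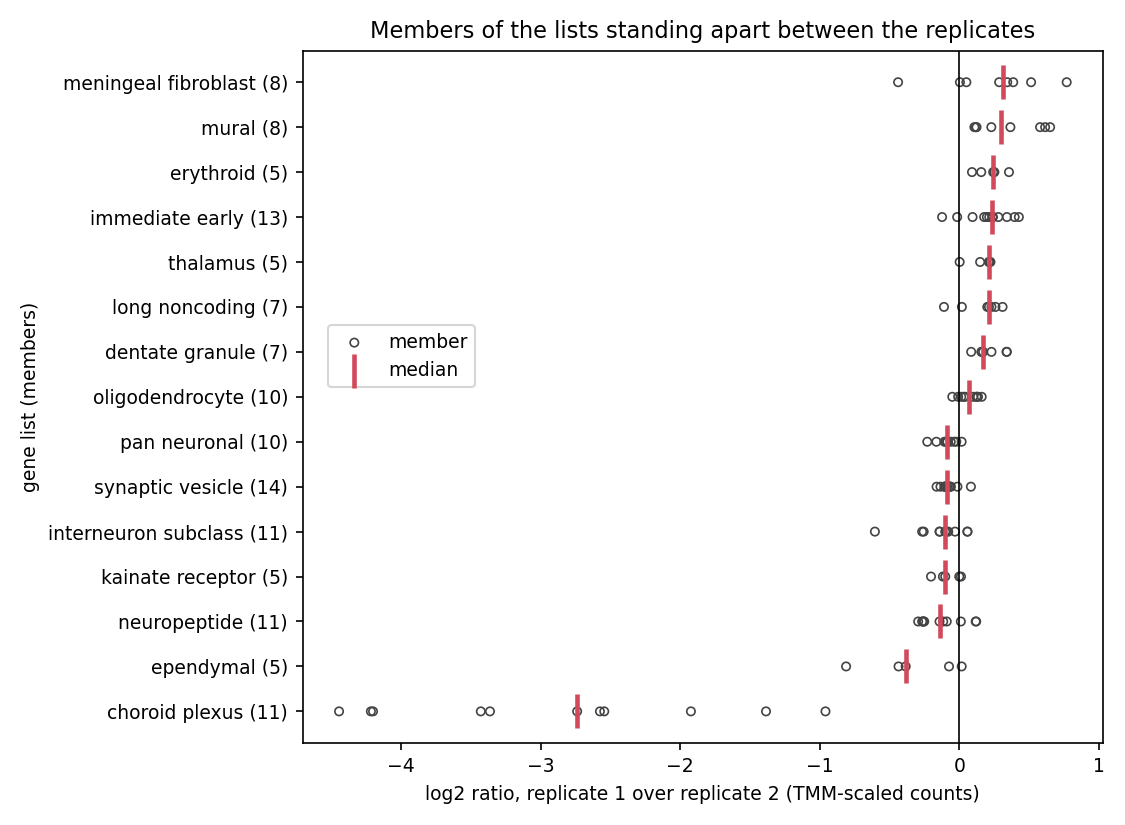
Log2 ratio of replicate 1 over replicate 2 (TMM-scaled counts) for the members, with a mean CPM of at least 1, of the 15 lists that stood apart; circles are genes and vertical bars are list medians. The choroid plexus list lies far to the left, with a median of -2.74, and the other medians lie between -0.39 and 0.31.

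Transcript levels came from 2 quantifications per library, called here the first and the second transcript table. The leading transcript, the one with the highest mean TPM, was the same in both for 76.2% of 12115 genes with several transcripts. Of the 20 genes fixed beforehand, 19 had the same leading transcript in both, the exception being Grin1, where Grin1-201 led in the first (39.3% ± 1.04) and Grin1-205 in the second (32.9% ± 0.361). App-201, which codes for the 695 amino acid form of the amyloid precursor, held 91.6% ± 0.113 of the gene's TPM in the first and 90.1% ± 1.08 in the second table. Mapt-204 held 66.8% ± 0.218 and 74.3% ± 2.44, and Snap25-201 88.9% ± 0.265 and 86.4% ± 0.586. For Ntrk2, transcripts of the full-length receptor, 821 amino acids, held 40.2% ± 0.305 and those of the truncated receptor of 476 amino acids 48.0% ± 1.14; the second table gave 42.5% ± 0.00494 and 49.5% ± 0.742. With Ntrk2-205 and the others that code for 466 to 492 amino acids, the shorter forms held 58.7% ± 0.554, and 54.6% ± 0.343 in the second table. For Homer1, transcripts that code for 186 or 193 amino acids held 59.5% ± 1.54 and those for 366 or 370 amino acids 34.9% ± 2.24; the second table gave 51.5% ± 1.82 and 28.0% ± 0.480. The tables gave different shares for Mbp-211 (71.7% ± 0.742 and 41.9% ± 1.68) and Dlg4-203 (59.96% ± 0.502 and 29.99% ± 0.509), gaps far beyond the SD. Bdnf-205 held 44.3% ± 7.75, and the next transcript, Bdnf-209, 34.5% ± 7.77, a difference that is not beyond the spread in the first table, where Bdnf-209 led in replicate 1 and Bdnf-205 in replicate 2. In the second table Bdnf-205 led in both, with 47.9% ± 0.780 against 35.6% ± 5.39.

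**Figure D4:**
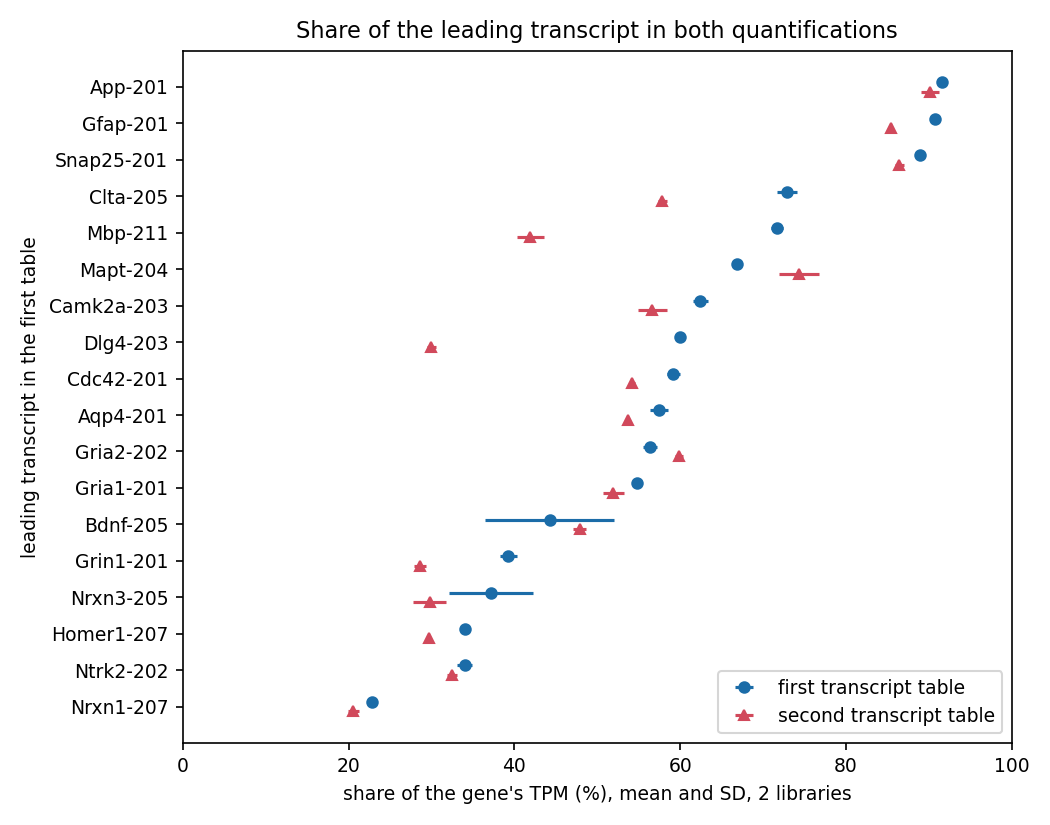
Share of the gene's TPM held by the leading transcript of genes from the list fixed beforehand, in percent, as the mean with SD over the 2 libraries; circles are the first and triangles the second transcript table. App-201 holds the largest share in both tables, 91.6% and 90.1%, and Mbp-211 and Dlg4-203 differ most between them.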

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

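The test of the second choroid plexus list and the 3 tests of intronic and antisense transcripts were fixed before their results were seen; those of Ttr alone, the meninges, antisense genes alone and mt-Co2 were chosen afterwards.

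The rows named by a number only, laid out like transfer RNA entries, were used in no comparison. Together they held 7.87 expected counts in replicate 1 and 3.85 in replicate 2, and 6 of the 26248 rows had any count. No biological explanation was tested.

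The higher choroid plexus genes in replicate 2 may come from choroid plexus, which lies beside the hippocampus, carried over in the dissection: a second list of 16 choroid plexus genes with a mean CPM of at least 0.1, fixed before its values were seen, had a median log2 ratio of replicate 1 over replicate 2 of -1.53, with 15 of 16 genes higher in replicate 2. A change of Ttr alone is argued against by the 11 other members of the first list, whose median was -2.74. Meninges carried over with the choroid plexus are argued against by the meningeal fibroblast genes, whose median was 0.31. Of these, 7 were higher in replicate 1 and 1, Igf2, in replicate 2. Over members with a mean CPM of at least 5 their median was 0.14. The values behind both tests were known when the tests were chosen, so neither is independent of the pattern. Ttr, the most abundant choroid plexus gene, stood at 672 TPM in replicate 2 and 29.9 TPM in replicate 1. Some listed genes were present in both libraries with smaller differences, among them Enpp2 (57.8 TPM in replicate 1), Kl (4.60 TPM), Cab39l (9.04 TPM), Car12 (18.1 TPM) and Slc29a4 (18.0 TPM), so hippocampal cells or choroid plexus in both pieces may supply them. Apart from Ttr alone, no biological explanation was tested, since there is 1 group, and a difference between the animals or tissue pieces stays open.

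Transcripts annotated as intronic, unconfirmed or antisense were higher in replicate 1, with a median log2 ratio of 0.20 over 705 genes, 74.2% of them above 0, carried by the 495 unconfirmed (0.26) and 43 intronic genes (0.24), while the 167 antisense genes had a median of 0.06, 58.7% of them above 0. Low expression is argued against, since the highest median among 10000 draws of protein-coding genes matched on expression was 0.0610, and for antisense genes alone 1.02% of the draws reached their median. The log2 ratio was also fitted linearly on GC content and length over protein-coding genes. For the whole, the median residual from this fit was 0.21. This argues against a linear effect of the size seen in protein-coding genes. The fit cannot exclude an effect of another shape, or one particular to these classes. For antisense genes alone the median residual was 0.0705 with a standard error of 0.0260, which leaves them open. A larger share of unprocessed or nuclear RNA in replicate 1 is a candidate explanation: within 4775 genes, transcripts with a retained intron against the coding transcripts of the same gene had a median log2 ratio of 0.18. No biological explanation was tested, nor whether this bears on the long noncoding RNA and immediate early lists, with medians of 0.21 and 0.24.

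The log2 ratio of mt-Co2, 0.78, lay above those of the other 12 mitochondrial messenger RNAs, -0.13 to 0.22. Gm28661 on chromosome 1 (24614885 to 24615565, mm10) matches mt-Co2 over 681 bases at 100% identity and held 103766 and 99159 counts against 3578 and 1979 for mt-Co2. Summed with its copies, mt-Co2 differed from the median of the others by -0.0176. Gm28661 held most of the summed counts and had a log2 ratio of -0.00921, so the sum would lie near that value whatever mt-Co2 did. The test therefore cannot tell whether the ratio of mt-Co2 alone comes from how shared reads were divided. No biological explanation was tested.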

How the results depend on the processing

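The alternatives without choroid plexus genes, without uncertain genes, without members shared between lists and with spike-in scaling over the same genes were chosen after seeing the data. No paired analysis was possible because there is 1 group. The mitochondrial share was 12.045% as a share of TPM. The log2 ratio of excitatory to inhibitory lists was 2.71 with counts not corrected for length and 2.56 with the mean of log2(TPM + 1), and that of neuronal to glial lists 2.81 and 2.38. The count of genes differing at least 2-fold, 16, was 77 with a mean CPM of at least 1, 3881 with no minimum, 14 in the second table (9 shared), 12 without the genes of the choroid plexus lists, 10 when Ace and F5, picked for their ratios, were left out as well, and 8 without pseudogenes and uncertain genes; it stayed at 16 with DESeq2 size factors and with spike-in scaling, where 13 genes were shared. Leading transcripts were the same in both tables for 88.0% of genes where the leading one held at least 60% of the gene's TPM, and for 75.1% to 75.3% with each replicate left out. Spike-in scaling reversed the median log2 ratios of pan-neuronal (0.0900), interneuron subclass (0.0768), kainate receptor (0.0767), synaptic vesicle (0.0865) and neuropeptide (0.0359) genes, since it moved all genes by 0.18; the cause of the other changes was not tested. Between 11 and 16 lists stood apart, 11 of them without shared members, and 8 of the 15 did in every setting; spike-in scaling gave 14, and 15 over the same genes. List medians in TPM moved: with TPM rescaled over protein-coding nuclear genes all 47 were higher, 2.40 times at the median; 37 moved by over 1.5 times with the second table, with counts not corrected for length 31, and with members at a TPM of at least 1 only, 10 of 44; with each replicate left out 3 did, choroid plexus and lymphocyte in both cases, mural cell without replicate 1 and senescence without replicate 2; the lists above random numbered 16 to 19 throughout. The choroid plexus median, -2.74, was -1.92 over members with a mean CPM of at least 5. The coefficient of variation lay between 3.87% and 5.03%, counted as unchanged if within 1.5 times, since 2 libraries give it no spread of its own. Genes detected in both libraries numbered 10363 at a TPM of at least 5 and 20382 at 0.1. Depth limits what a count of 0 can show to the levels in CPM given with the depth.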

Other observations

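The values in this part were compared after the results were seen, and only mt-Co2 was tested, as given above. The ratio of mt-Co2 was 0.78 in the gene table and 0.30 in the second table. The imprinted gene Cdkn1c had a log2 ratio of -1.05 and Igf2 of -0.44.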
